A study of Homo sapiens with 6 samples.

How the data were processed

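The data are 6 one-colour Illumina bead arrays (human HT-12 version 4 content) of total RNA from U251 cells, an established human glioblastoma line. Cells had been transduced with lentivirus for 5 days before RNA was taken. 3 arrays carried RNA of cells with a non-target shRNA (shCON) and 3 arrays carried RNA of cells with an shRNA against cyclophilin B (shCypB). The labels call the 3 samples of each group biological replicates. The RNA was biotin labelled and had been isolated with a column kit that keeps small RNA, per the labels' protocols.

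The authors deposited 2 tables. In the first, the deposited values are the bead signal intensity of each of 47231 probes on each array, on a linear scale and not normalized between arrays, per the file headers. Beside each intensity the authors deposited a detection p-value, which says how often a negative control bead was at least as bright. It moves in steps of 1 in 770. The second table holds the authors' processed intensity of the same arrays. These values were linear, not centred, and ranked the probes of each array like the non-normalized signals of that array (Spearman rho 0.999 or higher), against 0.891 or less for any other array. Their medians were 80.0, 78.5 and 80.4 on the shCON arrays and 77.9, 79.6 and 78.3 on the shCypB arrays. Partek is named, without a version or a role, in the submitters' processing notes, and the normalization method behind that table is not given in the sources used here. It was used only as an alternative. The files name no slide, so the slide could not be entered as a block.

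Signals were background corrected with the normexp method of limma 3.58.1 (R 4.3.3), with the negative control mean and spread inferred from the detection p-values and an offset of 16. They were then quantile normalized over the 6 arrays and log2 transformed. A probe was tested if its detection p was below 0.05 on at least 3 of the 6 arrays, which left 17608 probes. Median signals before correction lay between 75.4 and 82.3, and 16597 to 18700 probes (35.1% to 39.6%) were detected per array. The number of arrays, 3 per group, limits the precision. The log2 signals were fitted with limma's lmFit and eBayes with the group as the only term (4 residual and 3.51 prior degrees of freedom), and p-values were adjusted by the Benjamini-Hochberg method over the 17608 probes. A probe was called at an adjusted p below 0.05. The adjusted p of a single gene comes from this limma fit, except where the text names an alternative, whose limma fit then gives it. Errors beside log2 changes are its standard errors, and errors beside group means are SDs of 3 arrays. An exact permutation test of 3 against 3 arrays cannot go below a two-sided p of 0.1, so none was run on single genes.

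For a probe undetected on all 3 arrays of a group, the fold is a bound, written "at least N-fold". It sets the other group's mean against the mean, over the dim group's arrays, of the higher of the probe's own value and the lowest value among detected probes. These floors lay between 5.12 and 5.29 on the log2 scale.

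The probe table names 1 gene symbol for 30113 probes and several for 8, and does not list 17110. Symbols were updated through their Entrez identifiers to the RefSeq annotation of the GRCh38.p14 assembly, which was used for names, gene classes, gene lengths and neighbours only. No coordinates are printed, because the probe table states no build. Of the tested probes, 13793 named 1 gene, 3 several and 3812 none. A gene was represented by its tested probe with the highest mean over the 6 arrays, which gave 10517 genes. Of 2666 genes with at least 2 tested probes, 22 had probes called in opposite directions.

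Before the data were examined, 32 gene lists were written that fit the cells, the targeted protein and the other cell types a sample could hold. 31 of them had at least 5 tested members. They were tested with camera (limma) at a preset correlation of 0.01 between genes, two-sided, with Benjamini-Hochberg adjustment over the 31 lists. Camera with an estimated correlation and fry were run beside it. The genes named in the text were fixed by a rule written at the same time. It takes a study panel (PPIB, MYC, JAK2, STAT3, CHEK1, CDKN1A, EGFR, HRAS, MAPK3, AKT1, BSG and MAX), the 10 genes that rose most and the 10 that fell most among called genes whose groups did not overlap, leaving out open reading frames, pseudogenes and unnamed loci, and up to 4 called members of each list with the greatest changes, or the 2 with the smallest p where none was called. List members may be left out of the text.

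The fit was tested on simulated data for this comparison, with the probes' own means and SDs and 200 of 17608 probes changed. It called 24.0% of 50 probes changed 1.5-fold, 68.0% of 50 changed 2-fold, 82.0% of 50 changed 3-fold and 96.0% of 50 changed 4-fold, all in the right direction, and 11 of its 146 calls were unchanged probes. Over 10517 simulated genes, camera called 20 of 20 lists moved by 0.50 on the log2 scale and 1 of 200 unmoved lists. Simulated genes were independent, which real genes are not. The real comparison called 38.5% of probes, a far larger share than was changed in the simulation. The adjustment depends on that share, so the simulated rates need not hold for the real fit.

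Alternatives written before the data were examined were no background correction, normexp without negative controls at an offset of 50, scaling to a common 75th percentile, cyclic loess, no filter on dim probes, detection at p below 0.01 on all 6 arrays, trended and robust eBayes, array weights, the authors' processed values, the replicate number as a block, each array left out in turn, the mean of a gene's probes, a minimum change of 1.5-fold and both other list tests. Removing the trend of signal with gene length was added after seeing the data.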

Results

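Gene expression was measured in U251 glioblastoma cells 5 days after lentiviral transduction with a non-target shRNA (shCON, 3 arrays) or with an shRNA against cyclophilin B (shCypB, 3 arrays). Cyclophilin B, encoded by PPIB, is a prolyl isomerase of the endoplasmic reticulum, and the series addresses its part in the survival of glioblastoma cells. The arrays carried 47231 probes, of which 16597 to 18700 were detected per array. Log2 signals correlated with Pearson r of 0.987 to 0.994 between arrays of one group (6 pairs) and 0.957 to 0.965 between groups (9 pairs). The first principal component held 71.3% of the variance and separated the groups.

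The targeted gene was lower on each shCypB array than on each shCON array. PPIB had a log2 signal of 6.05, 5.68 and 5.35 on the shCON arrays and 4.58, 4.44 and 4.81 on the shCypB arrays, a log2 change of -1.08 ± 0.19 (adjusted p = 0.0034). Its only tested probe was dim, which is unusual for a transcript known to be abundant in most cells, and whether the probe reads the main PPIB transcript was not checked. It was detected on 3 shCON arrays and on 0 shCypB arrays, so the fall is given as at least 1.45-fold.

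In shCypB cells, genes of DNA replication and mitosis fell together. The cyclin-dependent kinase inhibitor gene CDKN1A, target genes of ERK signalling and senescence-associated secretory genes rose. The arrays hold no other shRNA against cyclophilin B, so its loss and other effects of this shRNA cannot be told apart. DNA replication and G1/S genes fell by 0.69 in median on the log2 scale and G2/M and mitosis genes by 0.53, and ERK output and secretory genes rose by 0.67 and 0.82 (0.80 with the 2 secretory genes undetected in 1 group at their bounds). Each of these 4 lists had an adjusted p = 0.25 with an estimated correlation. The cytokine gene IL11 rose 48.3-fold, with a log2 signal of 5.60 ± 0.17 in shCON and 11.20 ± 0.11 in shCypB (SD, n = 3). Its shCON signal was little above background, so the size of this fold depends on the background correction. Within the study panel, CDKN1A rose 2.66-fold and the transcription factor genes MYC and STAT3 and the checkpoint kinase gene CHEK1 fell by less than 1.5-fold. A total of 3570 of 17608 probes were higher in shCypB and 3205 were lower, and with a change of at least 1.5-fold the counts were 1927 and 1858. By gene, 2426 of 10517 rose and 2184 fell, 417 and 429 of them by at least 2-fold. The 3 values of each group did not overlap for 56.8% of genes, against 10% by chance.

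**Figure D1:**
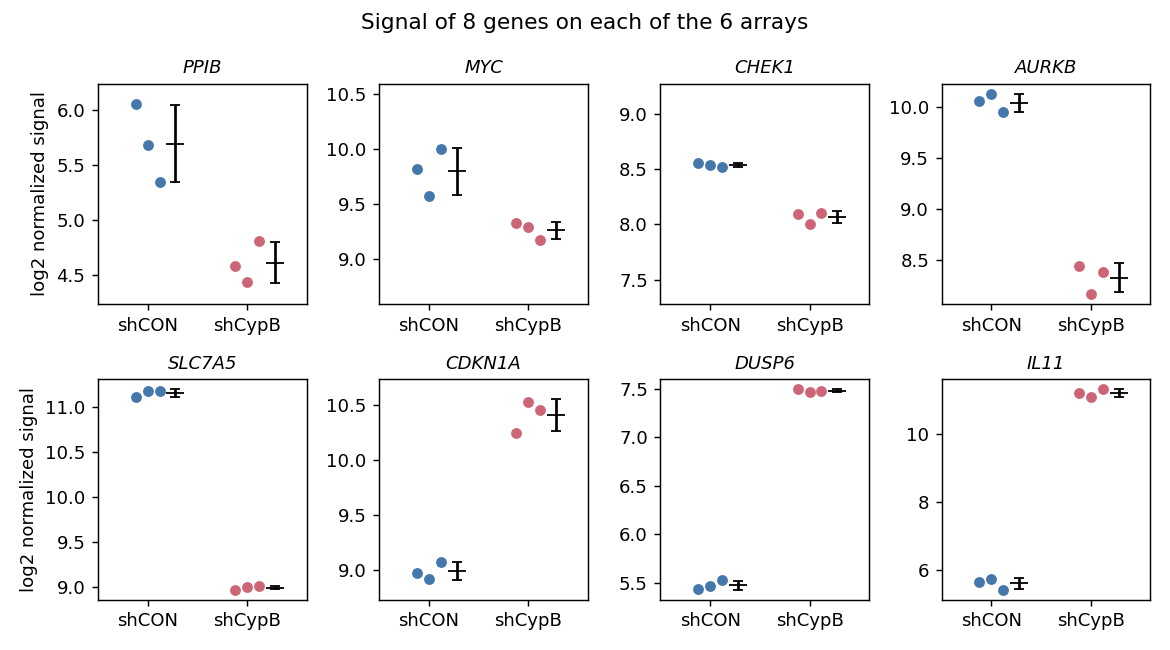
Log2 normalized signal (y axis, with its own range in each panel) of 8 genes on the 3 shCON arrays (blue) and the 3 shCypB arrays (red), with the group mean and SD in black. PPIB, MYC, CHEK1, AURKB and SLC7A5 were lower on each shCypB array than on each shCON array, and CDKN1A, DUSP6 and IL11 were higher, with IL11 at a mean of 5.60 against 11.20.

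Among genes of signalling and growth chosen for the study panel, CDKN1A had the greatest measured log2 change. Its log2 signal was 8.99 ± 0.08 in shCON and 10.41 ± 0.14 in shCypB (SD, n = 3), a log2 change of 1.41 ± 0.11 (adjusted p = 0.00013). MYC, a driver of cell growth, fell by 0.53 ± 0.13 on the log2 scale (adjusted p = 0.014). STAT3 fell by 0.46 ± 0.10 (adjusted p = 0.010; 1 of its 3 probes, at -0.28, did not pass) and CHEK1 by 0.47 ± 0.09 (adjusted p = 0.0048). MAPK3, which encodes the kinase ERK1, fell by 0.69 ± 0.11 (adjusted p = 0.0028). The receptor gene EGFR rose by 0.41 ± 0.10 (adjusted p = 0.014), a call that was lost when its probes were averaged (log2 change 0.31, adjusted p = 0.091). JAK2 (0.14 ± 0.14, adjusted p = 0.48), HRAS (-0.05 ± 0.10, adjusted p = 0.74), AKT1 (-0.05 ± 0.09, adjusted p = 0.73) and MAX (0.29 ± 0.27, adjusted p = 0.44) did not pass, nor did BSG, which encodes the cell surface protein basigin (0.19 ± 0.11, adjusted p = 0.22). For MAX the call depended on 1 array, since without shCON replicate 3 its log2 change was 0.63 (adjusted p = 0.025).

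Ranked by fitted log2 change, the first 10 risen genes were IL11, CGB5, GDF15, LHB, CGB1, SNORA62, ASGR1, SCARNA13, BIK and CXCL8. The places of LHB, ASGR1, SCARNA13 and BIK rest on shCON signals at background and are not settled. IL11, CGB5, GDF15, CGB1 and SNORA62 were also dim in shCON. Means were 5.60 for IL11, 5.78 for CGB5 and 5.72 for GDF15, against shCON floors of 5.15 to 5.29. The sizes of their changes therefore depend on the background correction. GDF15, a stress-induced secreted protein of the TGF-beta family, had a log2 change of 3.38 ± 0.19. CGB5 (3.40 ± 0.14, and 0.91 at its other probe) and CGB1 (3.11 ± 0.10) belong with LHB to the gonadotropin beta subunit cluster. These genes are near-identical, so their probes may share signal and the gene of origin is uncertain. LHB was undetected on all shCON arrays and rose at least 7.29-fold. The hepatic lectin receptor gene ASGR1 rose at least 5.31-fold, the small Cajal body RNA SCARNA13 at least 5.24-fold and BIK, a pro-apoptotic BCL2 family member, at least 4.12-fold, each undetected on all shCON arrays. SNORA62, a small nucleolar RNA detected on 2 of 3 shCON arrays, had a log2 change of 3.09 ± 0.24. The chemokine gene CXCL8 had a log2 change of 2.85 ± 0.43, with the shCON arrays spread by an SD of 0.94.

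By the same ranking the first 10 fallen genes were PI15, SERPINA3, HRCT1, UCP2, EMC4, KCTD12, TMEM141, HCP5, FAM120AOS and DEPP1. The place of UCP2 rests on shCypB signals at background and is not settled. PI15, a secreted peptidase inhibitor, fell by 3.14 ± 0.10 on the log2 scale, and SERPINA3, an acute-phase protease inhibitor, by 3.08 ± 0.09 from a log2 signal of 11.48 ± 0.09 (SD, n = 3). EMC4, a subunit of the endoplasmic reticulum membrane protein complex, fell by 2.64 ± 0.12. UCP2, a mitochondrial carrier, was undetected on all shCypB arrays and fell at least 5.04-fold. Adjusted p of these 20 genes was 0.0018 for CXCL8 and 0.00015 or lower for the others.

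Of the 31 gene lists, 4 fell and 3 rose by camera at its preset correlation, and 0 did so with an estimated correlation, where the lowest adjusted p was 0.25. Of 36 tested DNA replication and G1/S genes, 32 fell, 0 rose and 4 did not pass (adjusted p = 1.4e-11 for the list, and adjusted p = 0.25 with an estimated correlation). Adjusted over the list alone, 33 fell. RRM2, a subunit of ribonucleotide reductase, fell by 1.36 ± 0.11 on the log2 scale, the transcription factor gene E2F2 by 1.28 ± 0.10 and the thymidine kinase gene TK1 by 1.23 ± 0.11. GINS4, part of the replicative helicase, was undetected on all shCypB arrays and fell at least 1.76-fold. Of 43 G2/M and mitosis genes, 30 fell, 0 rose and 13 did not pass (adjusted p = 1.9e-09, and adjusted p = 0.25 with an estimated correlation), and 31 fell adjusted over the list alone. The kinetochore gene SPC24 fell by 1.88 ± 0.10, the mitotic kinase gene AURKB by 1.72 ± 0.11, and the kinesin genes KIF20A and KIF23 by 1.54 ± 0.12 and 1.51 ± 0.10.

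Genes of the DNA damage checkpoint and homologous recombination fell as a list, with 16 of 30 lower, 2 higher and 12 that did not pass (adjusted p = 0.0030, and adjusted p = 0.25 with an estimated correlation). Adjusted over the list alone, 17 fell and 4 rose. The checkpoint mediator gene MDC1 fell by 1.17 ± 0.10, the recombination genes RAD54L and XRCC3 by 1.14 ± 0.12 and 1.13 ± 0.12, and FANCG, of the Fanconi anaemia core complex, by 1.01 ± 0.09. Of 24 tested p53 target genes, 5 rose, 3 fell and 16 did not pass (adjusted p = 0.59), with 5 and 3 adjusted over the list alone. Its risers were led by GDF15, SESN1 (log2 change 1.64 ± 0.14), CDKN1A and the ubiquitin ligase gene FBXW7 (1.12 ± 0.11, with its 3 probes between -0.07 and 1.12). Its greatest fall was that of BAX (-0.80 ± 0.11, and -0.19 at its other probe). The list had a median log2 change of 0.01 and a mean of 0.26.

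ERK pathway output genes rose as a list (adjusted p = 4.0e-06, and adjusted p = 0.25 with an estimated correlation). Of 23 tested genes, 18 were higher, 4 did not pass and 1, MYC, was lower, by 0.53 on the log2 scale. Their median log2 change was 0.67, and 19 rose adjusted over the list alone. The ERK phosphatase genes DUSP5 and DUSP6 rose by 2.33 ± 0.10 and 2.01 ± 0.09 on the log2 scale, the growth factor gene HBEGF by 2.08 ± 0.10, and SPRY2, a feedback inhibitor of receptor tyrosine kinase signalling, by 1.86 ± 0.10. Of 35 senescence-associated secretory genes on the array, only 18 were detected widely enough to be tested. Of these 18, 13 rose, 1 fell and 4 did not pass (adjusted p = 4.1e-05, and adjusted p = 0.25 with an estimated correlation). The counts adjusted over the list alone were also 13 and 1. IL11, GDF15 and CXCL8 led this list, followed by the urokinase receptor gene PLAUR (1.71 ± 0.10). Of 15 senescence regulators and lamina genes, 8 rose, 2 fell and 5 did not pass (adjusted p = 0.13), and 10 rose and 3 fell adjusted over the list alone. They include the cyclin-dependent kinase inhibitor gene CDKN1B (1.21 ± 0.09) and HMGB2, a chromatin protein gene that fell by 0.86 ± 0.14.

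The list of ATF4 and CHOP stress response genes fell, with 14 of 24 lower, 4 higher and 6 that did not pass (adjusted p = 0.0029, and adjusted p = 0.25 with an estimated correlation). Adjusted over the list alone, 15 fell and 4 rose. The members that fell most serve amino acid supply and tRNA charging or are stress-induced. SLC7A5, a transporter of large neutral amino acids, fell by 2.17 ± 0.09 on the log2 scale, PHGDH, the first enzyme of serine synthesis, by 1.39 ± 0.09, the alanyl-tRNA synthetase gene AARS1 by 1.09 ± 0.09 and the stress-induced nuclear protein gene NUPR1 by 1.45 ± 0.13. Of 26 genes of endoplasmic reticulum chaperones and degradation, 7 rose, 8 fell and 11 did not pass (adjusted p = 0.79), with 7 and 9 adjusted over the list alone. XBP1, a transcription factor of the unfolded protein response, fell by 1.45 ± 0.09 and the disulfide isomerase gene PDIA4 by 1.20 ± 0.20, whereas the co-chaperone gene DNAJB9 rose by 0.85 ± 0.12 and the oxidase gene ERO1A by 0.85 ± 0.10.

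**Figure D2:**
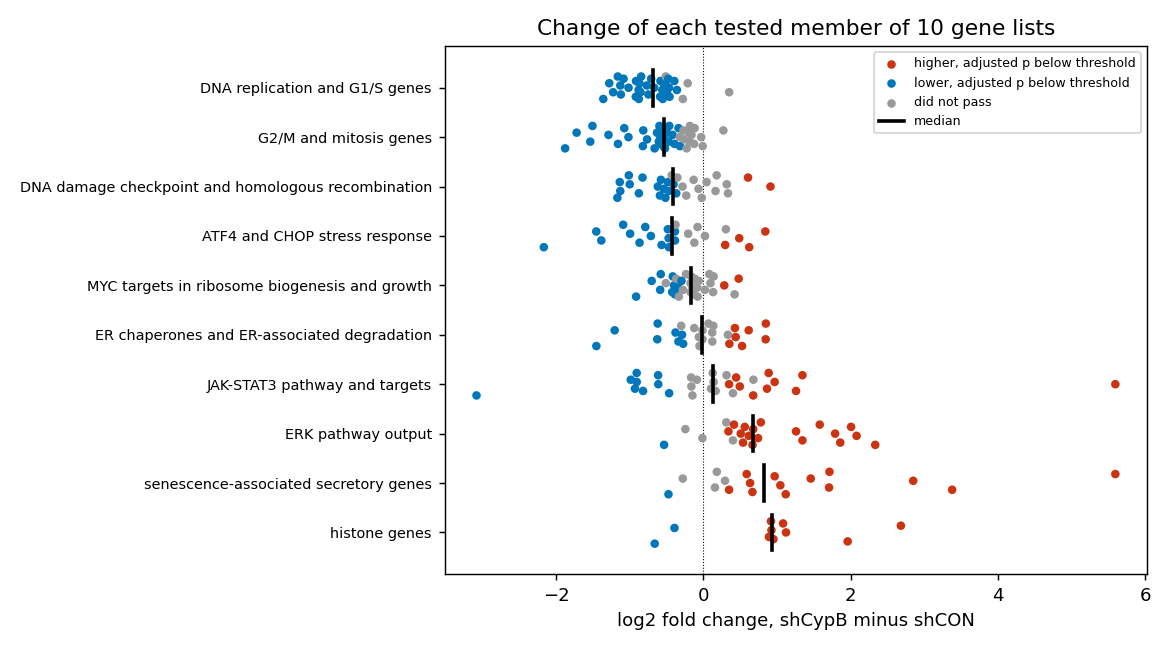
Log2 fold change (x axis, shCypB minus shCON) of each tested member of 10 gene lists (y axis). Each point is a gene, red where it rose, blue where it fell and grey where it did not pass, and the black bar is the list's median, which was -0.69 for DNA replication and G1/S genes and 0.67 for ERK pathway output.

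Of 17 histone genes in the list 10 were tested, of which 8 rose and 2 fell (adjusted p = 0.016, and adjusted p = 0.38 with an estimated correlation). The counts adjusted over the list alone were the same. H2BC21 rose by 1.96 ± 0.28 on the log2 scale, H2BC5 by 1.12 ± 0.12 and H2AC18 by 1.08 ± 0.11, and H2AC6, detected on 1 of 3 shCON arrays, had a log2 change of 2.68 ± 0.27. Histone genes of a class are alike in sequence, so their probes may share signal. Which form of the histone transcripts was labelled and read by the probes was not checked. The list did not pass when probes had to be detected at p below 0.01 on all 6 arrays (adjusted p = 0.21).

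Lists linked to MYC and STAT3 did not pass. Of 32 MYC targets in ribosome biogenesis and growth, 10 fell, 2 rose and 20 did not pass (adjusted p = 0.068), and 11 fell and 3 rose adjusted over the list alone. The ribosome biogenesis gene PPAN fell by 0.91 ± 0.17, the spermidine synthase gene SRM by 0.70 ± 0.12 and CAD, of pyrimidine synthesis, by 0.59 ± 0.12. With the mean of a gene's probes this list fell (adjusted p = 0.035). Of 30 genes of the JAK-STAT3 pathway, 10 rose, 9 fell and 11 did not pass (adjusted p = 0.70), with 11 and 9 adjusted over the list alone. Its members moved apart, IL11, LIF (1.34 ± 0.14) and CCND1 (1.26 ± 0.09) upward and SERPINA3 downward.

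Among 14 tested cyclophilins other than PPIB, which the list leaves out, 2 rose, 2 fell and 10 did not pass (adjusted p = 0.91), with the same counts adjusted over the list alone. PPIL1, a nuclear cyclophilin of the spliceosome, fell by 1.76 ± 0.09 on the log2 scale, LRR1, formerly listed under a cyclophilin name, by 0.62 ± 0.11, and PPIC, another cyclophilin of the secretory pathway, rose by 0.56 ± 0.12. This list had a median log2 change of 0.09 and a mean of -0.06. Of 12 FKBP and parvulin isomerases, 2 rose, 1 fell and 9 did not pass (adjusted p = 0.70). FKBP1A rose by 0.71 ± 0.12 and FKBP15 by 0.69 ± 0.13, and FKBP14, of the endoplasmic reticulum, fell by 0.86 ± 0.16. Collagens, whose folding involves cyclophilin B, rose in 7 of 17 cases, fell in 2 and did not pass in 8 (adjusted p = 0.21). COL1A1 rose by 1.72 ± 0.16, COL4A1 by 1.42 ± 0.10 and COL7A1 by 1.38 ± 0.16. Of 17 collagen modifying enzymes, 4 rose, 6 fell and 7 did not pass (adjusted p = 0.38), with the lysyl hydroxylase gene PLOD1 lower by 0.81 ± 0.10 and COLGALT1 higher by 0.83 ± 0.10. Adjusted over the list alone, 2 FKBP and parvulin genes rose and 1 fell, 8 collagens rose and 3 fell, and 4 collagen modifying enzymes rose and 6 fell.

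Lists of stress, survival and metabolism did not pass, although single members changed. BCL2 family and caspase genes rose in 8 of 27 cases and fell in 3 (adjusted p = 0.27), with BIK and PMAIP1 (0.90 ± 0.10), both pro-apoptotic, among the risers. BCL2L2, which encodes the anti-apoptotic protein BCL-w, fell by 1.52 ± 0.10 and the pro-apoptotic gene BAX by 0.80 ± 0.11 (its other probe, at -0.19, did not pass). Cytosolic heat shock genes fell in 6 of 20 cases and rose in 1 (adjusted p = 0.068), with CRYAB lower by 1.71 ± 0.11 and DNAJB1 by 1.09 ± 0.09, and this list fell with the mean of a gene's probes (adjusted p = 0.047). Of 20 NRF2 antioxidant genes, 3 rose and 7 fell (adjusted p = 0.23), AKR1B10 by 2.07 ± 0.11 and ABCC3 by 2.06 ± 0.10, while HMOX1 rose by 1.47 ± 0.13. Hypoxia and glycolysis genes rose in 8 of 31 cases and fell in 4 (adjusted p = 0.30), with the glucose transporter gene SLC2A3 (2.38 ± 0.12) and ADM (1.91 ± 0.09) higher and VEGFA lower by 0.91 ± 0.18 (its other probe, at -0.10, did not pass). Of 22 genes of cholesterol synthesis and uptake, 3 rose and 7 fell (adjusted p = 0.20), with SREBF1 lower by 1.22 ± 0.09 (1 of its 3 probes, at -0.34, did not pass). Of 24 lysosome and autophagy genes, 9 rose and 4 fell (adjusted p = 0.34). Interferon-stimulated genes rose in 10 of 27 cases and fell in 2 (adjusted p = 0.18), led by SAMD9 (1.01 ± 0.11), the RNA sensor gene IFIH1 (0.78 ± 0.16), the exonuclease gene ISG20 (0.77 ± 0.10) and the RNA sensor gene RIGI (0.76 ± 0.10). Adjusted over the list alone, the genes that rose and fell numbered 8 and 4 in the BCL2 family, 1 and 7 for heat shock, 3 and 7 for NRF2, 9 and 4 for hypoxia, 3 and 8 for cholesterol, 11 and 4 for lysosomes, and 10 and 2 for interferon.

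Lists of glioma states and of other cell types also did not pass. Glioma mesenchymal markers rose in 9 of 24 cases and fell in 4 (adjusted p = 0.28). TGFBI (1.08 ± 0.10) and TWIST1 (1.05 ± 0.12) were higher, and S100A4 was lower (log2 change -0.82). Of 18 neural stem and proneural markers, 4 rose and 6 fell (adjusted p = 0.27), among them FABP7 by 1.07 ± 0.14 and the intermediate filament gene NES by 0.66 ± 0.10. Of 9 astrocyte markers, 4 rose and 2 fell (adjusted p = 0.63). GFAP, the astrocyte intermediate filament, fell by 1.84 ± 0.14, whereas FGFR3 (log2 change 1.18), ALDH1L1 and SLC1A3 rose. The call of SLC1A3 was lost under some alternatives. Of 9 neuron markers, 5 rose and 2 fell (adjusted p = 0.21), with SYT1, detected on 1 of 3 shCON arrays, at a log2 change of 2.12 ± 0.13. Of 5 microglia and macrophage markers, 2 rose and 0 fell (adjusted p = 0.55), and of the 3 tested endothelial and pericyte markers 0 passed, too few for a list test. Of these, VWF (log2 change -0.52 ± 0.22, adjusted p = 0.10) passed under 4 alternatives, among them the removal of shCON replicate 3 (log2 change -0.76, adjusted p = 0.024), and PDGFRB (-0.25 ± 0.19, adjusted p = 0.36) under 1, scaling to the 75th percentile (log2 change -0.45, adjusted p = 0.044). For comparison, 38 ribosomal protein genes held 1 that rose and 5 that fell (adjusted p = 0.34), 37 oxidative phosphorylation genes 9 and 3 (adjusted p = 0.21), and 21 housekeeping and RNA quality genes 5 and 3 (adjusted p = 0.79). Adjusted over the list alone, the genes that rose and fell numbered 9 and 4 for mesenchymal, 4 and 6 for proneural, 4 and 2 for astrocyte, 6 and 2 for neuron, 2 and 1 for microglia and 0 and 0 for endothelial markers, 1 and 3 for ribosomal proteins, 6 and 2 for oxidative phosphorylation and 5 and 3 for housekeeping genes.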

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

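Removing the trend with gene length was chosen after the results were seen, and the other settings were fixed before the data were examined. Of 139 called named genes, 124 kept direction and call under every setting run, 15 lost the call under at least 1 and 0 changed sign. PPIB stayed lower and past the threshold in the 15 fits that tested its probe, with log2 changes from -1.26 (scaling to the 75th percentile) to -0.66 (normexp with an offset of 50) and adjusted p of 0.014 or less. Its probe was too dim to be tested under the stricter filter or without any shCON array. The count of higher probes lay between 2619 and 4024 and that of lower probes between 2610 and 3640, except at a change of at least 1.5-fold (1927 and 1858). The gene lists that passed numbered 6 to 9, except 0 with an estimated correlation and 27 with fry, which asks whether a list moves without comparing it with other genes. Adjusted p with an estimated correlation was 0.25 for the lists of DNA replication, G2/M, DNA damage checkpoint, ATF4 and CHOP, ERK output and secretory genes and 0.38 for histone genes. Histone genes also did not pass under the stricter filter (adjusted p = 0.21), where fewer probes are tested. Results that changed direction had not passed. HRAS had a log2 change of 0.032 with scaling to the 75th percentile and 0.15 with the length trend removed, and AKT1 of 0.0057 with that scaling. JAK2 moved to -0.031 with the length trend removed. With each array left out in turn, HRAS ranged from -0.092 to 0.013 (above 0 without shCON replicate 2) and AKT1 from -0.082 to 0.0038 (above 0 without shCON replicate 3). EGFR lost its call with the length trend removed (log2 change 0.23, adjusted p = 0.085). VWF, not called otherwise, was lower with scaling to the 75th percentile (log2 change -0.77, adjusted p = 0.0075), with the authors' values (adjusted p = 0.038), without shCON replicate 3 (adjusted p = 0.024) and with the length trend removed (adjusted p = 0.034). Among lists, JAK-STAT3 genes turned down under the stricter filter (adjusted p = 0.88), endoplasmic reticulum chaperones and ribosomal proteins turned up with the length trend removed (adjusted p = 0.87 and 0.30), and housekeeping genes turned down with fry (adjusted p = 0.80). With the length trend removed oxidative phosphorylation genes rose at camera's preset correlation (adjusted p = 0.015) but did not pass with an estimated correlation (adjusted p = 0.21). The cause of these changes was not tested. Same-numbered arrays of both groups did not deviate together (correlations of -0.0980, -0.109 and 0.0095), so the numbers were not taken as pairs. With the replicate number as a block, 3022 probes were higher and 2764 lower, and cyclophilins turned up (adjusted p = 0.97). With each array left out in turn, adjusted p of the cyclophilins ranged from 0.70 to 0.995, and they turned up without shCypB replicate 2. The slide block was not run because the files name no slide. The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 3570 higher probes, 3205 lower probes and 7 lists, the highest of the other splits 0, 0 and 6, and 1 of the 10 splits, the real one, reached each of these results. Every other split mixed both groups, so the group difference entered its residual variance and the 0 called probes say little. With 6 lists passing under a mixed split, a pass at camera's preset correlation is weak evidence by itself. Signal over background limits dim probes such as PPIB, whose fold is only a bound.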

Other observations

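The tests of other short RNAs, host genes and exosome genes and the removal of the length trend were chosen after the results were seen, and so were the genes here that the naming rule does not give, while the test of the length trend between arrays of one group was set before its result was seen. Of 11 tested small Cajal body RNAs, 10 rose and 1 fell, with a median log2 change of 1.38. SCARNA18 had a log2 change of 2.47, SCARNA8, undetected on all shCON arrays, rose at least 3.04-fold, and SCARNA10 had a log2 change of -1.02, beside its host gene NCAPD2 at -0.92. The median was the same with the 6 of these RNAs undetected on all shCON arrays set at their bounds. Of 40 H/ACA box small nucleolar RNAs, 16 rose, 1 fell and 23 did not pass, with a median log2 change of 0.24. Among the risers were SNORA12 (2.85) and SNORA63 (2.63), each detected on 1 of 3 shCON arrays. SNORA79, undetected on all shCON arrays, rose at least 3.03-fold. The telomerase RNA TERC, which carries the same H/ACA structure, rose by 2.09 on the log2 scale, RN7SK by 1.71, and 3 near-identical copies of U3, SNORD3A, SNORD3C and SNORD3D, by 1.80, 1.88 and 1.87. Of 23 C/D box small nucleolar RNAs other than U3, 1 rose, 6 fell and 16 did not pass, with a median log2 change of -0.23. The 3 U3 copies, all risen, were counted apart from them. Of 7 spliceosomal RNAs 3 rose, RNU4-2 (1.39), RNU1-3 (0.98) and RNU1-1 (0.59), 0 fell and 4 did not pass, among them RNU6-1 (-0.02). RN7SL1 (0.13) and the 4 tested Y RNAs did not pass. Whether the probes read mature short RNAs or longer precursors was not checked. Of 21 microRNA precursors 2 rose, 0 fell and 19 did not pass, with a median log2 change of 0.05. Only 5 of these were detected on all 6 arrays, and they are not among the other short RNAs counted next.

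Cajal body RNAs rose in 10 of 11 cases and H/ACA RNAs in 16 of 40. More short RNA in the labelled material of the shCypB arrays is a candidate explanation for these rises. It would raise other short structured RNAs too. Of 41 such RNAs 9 rose, 6 fell and 26 did not pass, with a median log2 change of 0.02 (95% bootstrap interval -0.12 to 0.21). These 41 include TERC, which carries the H/ACA structure, and count the near-identical U3 copies separately. The interval reaches past 0.17, so the explanation stays open. This value is 50% of the median change of all 51 Cajal body and H/ACA RNAs with undetected ones at their bounds. Host transcripts did not rise as a set. Of the 32 tested hosts of 37 Cajal body and H/ACA RNAs, 5 rose and 6 fell. Their median log2 change was -0.075 (interval -0.19 to 0.013), below 50% of the RNAs' own median (0.17). Hosts were assigned by position without regard to strand, and the arrays read transcript levels rather than transcription. Host transcription therefore stays open as an explanation. Slower trimming of tailed precursors is a hypothesis that also stays open. Of 13 genes of the exosome and of 3' end trimming, 0 rose, 3 fell and 10 did not pass. Those that fell were EXOSC2 (-0.78), EXOSC3 (-0.85) and TOE1 (-1.01), while DIS3 was at 0.35 and EXOSC9 at 0.31. Among all 10517 tested genes 2184 fell. The median of the 13 genes was -0.22. For this set limma's camera gave p = 0.039 at its preset correlation and p = 0.11 with an estimated correlation.

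Change also went with the length of the gene. Among 10038 protein-coding genes, Spearman's rho between length and log2 change was 0.22 across genes, which are not independent replicates. In the shortest of 5 length classes 34.5% of genes fell and 13.7% rose, and in the longest 31.6% rose. Arrays of one group differed by a rho of up to 0.124 in absolute size in 6 pairs. This is above 50% of the group value though below the 0.169 to 0.227 of the 9 pairs across groups. With 3 arrays per group, variation between arrays and an effect of the shRNA both stay open. The trend is an unlikely cause of the fall of the cell cycle genes, because with it removed from each array both the DNA replication and the G2/M list passed at camera's preset correlation (adjusted p = 1.2e-09 for the weaker, and adjusted p = 0.21 with an estimated correlation, where neither passed) and the smaller share of a median change that was left was 102%.

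Other values stood out by size. Besides CGB5, CGB1 and LHB, the chorionic gonadotropin beta genes CGB8 and CGB3 rose, with log2 changes of 1.57 and 1.06, each detected on 1 of 3 shCON arrays. PPIL1, another cyclophilin, fell by 1.76 ± 0.09 on the log2 scale (adjusted p = 3.7e-05). The sequence of the shRNA was not used here, so a match to PPIL1 was not checked. Effects of lower PPIL1 and of lower PPIB cannot be told apart in these arrays.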
